A study of Homo sapiens with 4 samples.

How the data were processed

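The data are ATAC-seq peak lists of AMO1 myeloma cells, 1 list for each of 4 libraries: empty vector, PHF19 overexpression, and the same 2 vectors with the title prefix IFN, which the labels do not explain. Per the labels' protocols, cells were transfected with the empty PCDH vector or the vector with PHF19, treated with DNase I to remove free DNA, lysed, and their nuclei treated with Tn5 before indexing and PCR. Each library was assigned to its group from its labels, and each group holds 1 library.

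Peaks were called by the authors for each library separately with MACS2 2.1.2, without a control, on paired fragments, at a q of 0.01, keeping duplicates and calling several summits within a peak, with an effective genome size of 3000000000, per the file headers. The submitters' processing notes also name bcl2fastq 2.17, Trimmomatic 0.38, DiffBind and the build hg38. The aligner, the read filters and any shift of the Tn5 cut sites are not given in the sources used here. The deposited pileup column is the signal, the coverage by whole fragments at the summit, and it is not scaled, per the file headers. The deposited -log10 p-value and -log10 q-value columns and the fold enrichment, a ratio to the local background, are the authors' values for each peak and were used to rank and filter peaks within a list, never to compare lists. Because duplicates were kept, fragments are not all independent molecules, and intervals cover counting error only.

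Depth differed between libraries. The file headers give 27.4, 18.2, 65.9 and 16.4 M (mega) fragments for empty vector, PHF19 overexpression, IFN empty vector and IFN PHF19 overexpression, with mean fragment lengths of 276, 273, 270 and 269 bp. The lowest peaks had 10, 8, 16 and 8 fragments at the summit, so weaker peaks could be called in the IFN empty vector library. Its header also names a different project folder from the other 3, which are alike in this. Summits were collapsed to 1 peak per interval, with the tallest summit as its height, and peaks on chromosomes 1 to 22 and X were used; 5, 3, 9 and 4 lines of the lists lay elsewhere.

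Before the data were examined, the comparisons, the 21 gene lists, the alternatives and the rule for named genes were fixed. The comparisons were PHF19 overexpression against empty vector in each pair and IFN-prefixed against not with each vector. A peak was one-sided when no peak of the other library overlapped it by at least 1 bp, and its share was given a 95% Wilson interval. Gene coordinates came from a RefSeq table on the same build as the files, for 19974 protein-coding genes. The table gives no strand, exons or transcripts, so a gene-end peak is one that reaches within 1000 bp of either end of the gene, and exon, transcript-start, GC content and sequence motif steps were not run. Within every list up to 2 members (interferon, MHC, plasma cell, B cell and Polycomb lists) or up to 1 member (the others) with a gene-end peak in one library alone were named by the rank of their peak, with the 3 highest-ranked one-sided gene ends and the 2 highest-ranked one-sided peaks elsewhere per direction, and PHF19 first. For uncharacterised loci with a LOC symbol and for GTF2H2C_2, whose table position was doubtful, no value is given. Recurrence of one-sided regions in both pairs was set against the number expected for independent pairs within 10 classes of peak rank.

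Comparing heights was added after the data had been seen. The height of a region was the tallest pileup divided by the library's fragments in M, the log2 ratio was centred on the median of all regions with a peak in both libraries, and its 95% interval is the exact one for a ratio of counts. Such a comparison covers only regions called in all libraries concerned. A list's median was placed among the medians of 10000 random gene lists of the same size matched on height in 10 classes, as a description of these libraries and not a test, its 95% interval was read from the ranks of its regions, which are not independent replicates, and lists with fewer than 5 regions were left out. The height-based genes are the 8 per direction for PHF19 overexpression and 6 per direction for the IFN prefix with the largest smaller ratio of both comparisons and a mean height of at least 1 fragment per M, a rule set after the data had been seen, and other list members were picked after their values were seen. 1 gene picked by this rule is not reported here. Bins of 5 Mb with at least 20 regions were called when their median passed 0.3 in both pairs, and the local median was taken over regions within 2.5 Mb.

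The steps were tested on simulated data. Overlaps were 100.0% equal to a direct count over 800 intervals, and on the real lists the counts equalled those of bedtools. Of unchanged simulated lists 3.0% fell outside the central 95%, and of lists of 30 genes shifted by 0.2 on the log2 scale 64.5% lay above that range. The simulated values were independent of each other, so these shares do not cover lists with neighbouring members. Independent simulated losses gave a recurrence ratio of 1.02 within rank classes and 1.36 without them. The simulated loss rate was the same for all regions of a class. The check therefore does not show what ratio independent losses give when the rate varies inside a class. Removing the local median took a correlation made by blocks alone from 0.32 to 0.05 and left one made by single regions at 0.52. The simulated block was longer than the window of the local median, so shorter blocks are not covered. Alternatives were a q of 1e-05, lists of equal length (44090 peaks), an overlap of 50% each way, peaks within 500 bp counted as shared, gene-end windows of 500 and 2000 bp, summits in place of peaks, and chromosome X left out. Those added after the data had been seen were the other empty vector library as partner, peaks that themselves lack an overlap, and for heights summits within 150 bp, the local median removed, a height trend removed, no centring and a floor of 1 fragment per M. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 were used.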

Results

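Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in AMO1, an established plasma cell line from multiple myeloma. The cells had been transfected with an empty PCDH vector or with the same vector carrying PHF19, a Polycomb-like protein that binds Polycomb repressive complex 2, the enzyme complex that methylates histone H3 to keep developmental genes silent. There were 4 libraries with 1 per group: empty vector, PHF19 overexpression, and an empty vector and a PHF19 overexpression library whose titles carry the prefix IFN. The labels do not explain that prefix, and the libraries are called IFN-prefixed here. The peak lists rested on 27.4 M (mega) fragments for the empty vector library, 18.2 M for PHF19 overexpression, 65.9 M for the IFN empty vector library and 16.4 M for IFN PHF19 overexpression. They held 49155, 44090, 69830 and 45825 peaks in that order, covering 42.1, 35.9, 61.7 and 36.3 Mb of hg38. Merged across libraries they formed 73729 regions, 35731 of which had a peak in all 4 libraries. With 1 library per group no comparison has a replicate of its own and no difference was tested. The PHF19 difference and the IFN-prefix difference can each be read in a pair of comparisons that share no library. The 95% intervals cover counting error only. Gene-end peaks reach within 1000 bp of either end of a gene. Strand was not known, so they can lie at the start of a gene or at its far end. Log2 ratios compare the height of the tallest summit of a region, in fragments per M, and are relative to the median ratio of all regions with a peak in both libraries. That median was -0.11 for PHF19 overexpression against empty vector, 0.17 for the same comparison in the IFN-prefixed pair, -0.09 for the IFN-prefixed against the other empty vector library and 0.11 for the IFN-prefixed against the other PHF19 overexpression library.

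PHF19 itself, the gene carried by the vector, lies at 120855651 to 120904128 on chromosome 9. Both PHF19 overexpression libraries held a narrow peak inside the gene that neither empty vector library held. In the PHF19 overexpression library it spanned 120857950 to 120858284, a length of 335 bp, with 144 fragments at the summit or 7.9 per M. The IFN PHF19 overexpression library had it at 120857960 to 120858282, 323 bp long, with 120 fragments or 7.33 per M. The summits lay 2442 and 2441 bp inside the lower end of the gene, and exon positions were not used here. By the ranking fixed for one-sided peaks away from gene ends, this was the highest-ranked peak on the PHF19 side of both comparisons. All 4 libraries also held the same set of 4 broader peaks inside the gene. Their median log2 ratio was -0.2 with PHF19 overexpression and -0.3 in the IFN-prefixed pair. No library had a peak within 1000 bp of either end of PHF19.

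**Figure D1:**
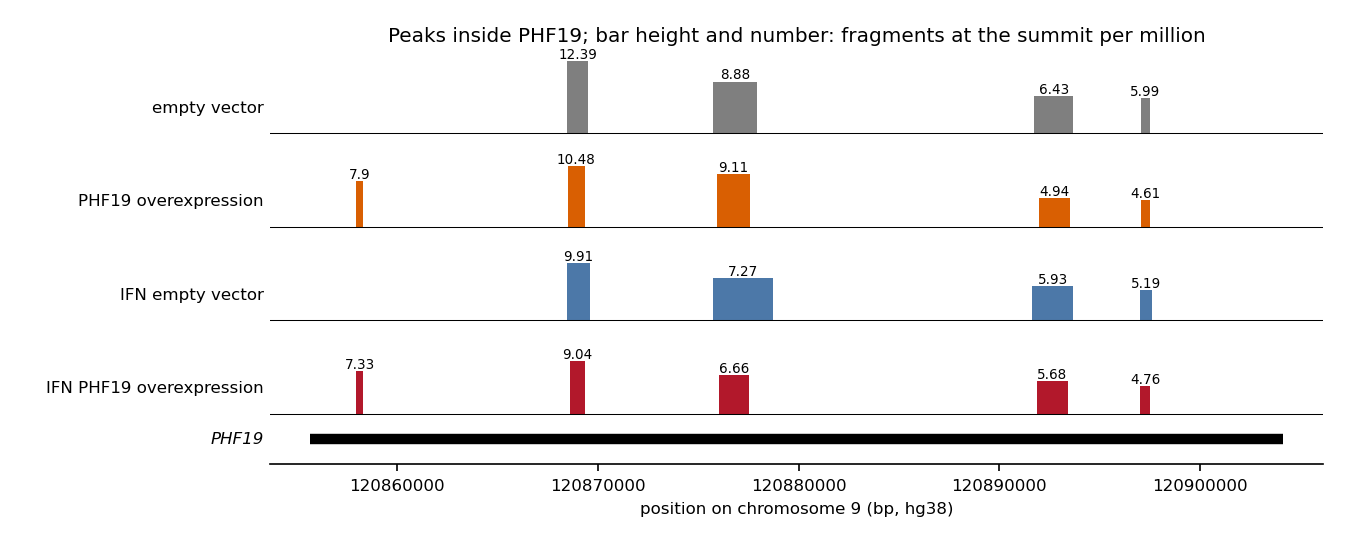
Peaks inside PHF19 on chromosome 9 (x axis, bp in hg38) in the 4 libraries; bar width is the extent of the peak, and bar height and the number above it give the fragments at its summit per M. The leftmost peak, at 7.9 and 7.33 fragments per M, appears in the PHF19 overexpression libraries and in neither empty vector library.

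The first comparison asks which open regions differ between cells with the PHF19 vector and cells with the empty vector. Classical Polycomb target genes, the developmental transcription factors that Polycomb keeps silent in most adult cells, stood higher at the gene ends open in all 4 libraries. Somewhat fewer of them had a gene-end peak with PHF19 overexpression, the library with fewer fragments. Among those with a gene-end peak in one library alone, 1 was on the PHF19 side and 4 on the empty vector side, a net count at the 8.9th percentile of matched random lists. When the peak itself had to lack an overlap, the counts were 1 and 2. The heights cover only members that kept a peak. The median log2 ratio of the 26 regions was 0.3 (95% interval over the regions 0.08 to 0.47), at the 99.9th percentile of 10000 random lists matched on height, and 21 regions lay above the random median. HOXC13, a posterior homeobox gene, had a log2 ratio of 1.27 (95% interval 0.74 to 1.81). MSX1, a homeobox gene of limb and tooth development, had 0.82 (0.39 to 1.25) and HOXD13, which patterns the digits, 0.4 (0.07 to 0.72). MHC class II presentation genes, which display peptides to helper T cells, had a median of -0.25 over 11 regions at the 1.2nd percentile, with an interval over the regions of -0.44 to 0.23 that includes 0. CD74, the invariant chain that guides class II molecules, was at -0.7 (-0.88 to -0.52) and HLA-DPB1, a class II beta chain, at -0.44 (-0.79 to -0.1). With the median of the surrounding 2.5 Mb on either side removed, the MHC class II list was at the 10.1st percentile, MSX1 at 0.36, HOXD13 at 0.2 and CD74 at -0.35. Many MHC class II genes lie side by side on chromosome 6, and the Polycomb target list also holds neighbouring genes, such as HOXA10 and HOXA11. The random lists were not matched on such clustering.

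Several lists of broadly active genes also lay low in this comparison. Housekeeping promoters, chosen as a control group of constantly expressed genes, had a median of -0.2 (interval -0.3 to -0.08) at the 0.9th percentile. The cereblon pathway and proteasome list, the machinery targeted by immunomodulatory drugs and proteasome inhibitors, had -0.21 (interval -0.32 to 0.05, 0.5th percentile), and the genes of the Polycomb complexes themselves had -0.15 (1.8th percentile, and -0.06 at the 19.3rd with the local median removed). Removal of the height trend left housekeeping promoters at -0.08 (1.0), cereblon and proteasome at -0.12 (0.3) and Polycomb complexes at -0.02 (12.8). The Polycomb complexes were at the 9.7th percentile under this setting in the IFN-prefixed pair. Among the Polycomb complex genes, EED, a core subunit of Polycomb repressive complex 2, was at -0.97 (-1.45 to -0.51), while PCGF3, of a variant Polycomb repressive complex 1, was at 0.88 (0.56 to 1.21), or 0.46 with the local median removed, and lies in a higher stretch of chromosome 4 described further on. Interferon-stimulated genes had a median of -0.05 over 36 regions (14.2nd percentile). Within that list IRF1, a transcription factor of the interferon response, was at 0.95 (0.64 to 1.27), or 0.64 with the local median removed, in a raised part of chromosome 5. IRF4, a transcription factor that myeloma cells depend on, was at -0.72 (-0.97 to -0.48) and CXCR4, a homing receptor for bone marrow, at -0.61 (-0.94 to -0.28), in a plasma cell list with a median of -0.12 (15.1st percentile). The other medians, with percentiles, were 0.06 for the B cell programme (73.2), -0.11 for interferon signalling (21.7), and -0.08 for MHC class I (42.8). Values were 0.01 for myeloma oncogenes and tumour suppressors (89.9), -0.17 for the unfolded protein response (8.6), and -0.15 for NF-kappaB (10.2). Immune ligands had -0.04 (35.1), apoptosis regulators -0.06 (69.5) and cell cycle genes -0.1 (38.6). IL6 and JAK/STAT3 genes had -0.18 (3.4, but -0.05 and 10.4 with a trend in height removed), T and NK cell markers 0.05 (49.5), myeloid markers 0.38 over 7 regions (94.9) and stromal and epithelial markers 0.02 over 7 regions (30.3). With the local median removed the direction turned for T and NK cell markers (-0.27, 0.5th percentile), myeloma genes (-0.05, 54.2), immune ligands (0.02, 51.4) and stromal and epithelial markers (-0.07, 13.1). NF-kappaB was at -0.02 (73.3), plasma cell identity at -0.14 (5.7) and housekeeping promoters at -0.15 (4.4).

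Peaks called in one library of this pair and not in the other were mostly low, with 107 of 5270 for PHF19 overexpression and 647 of 10563 for the empty vector in the upper 50% of their list by rank. Near the gene ends, the empty vector library alone held small peaks at the interferon-stimulated genes GBP1, a guanylate-binding protein (chromosome 1, 89064689 to 89065388, 15 fragments, 0.55 per M), and IFI44L (15 fragments, 0.55 per M). It also alone held peaks at CD22, a B cell receptor that dampens signalling (14 fragments), at ATF3, a stress-induced transcription factor (16), at the alpha globin gene HBA2 (12) and at CD2, an adhesion molecule of T cells (chromosome 1, 116769355 to 116770208, 42 fragments, 1.53 per M). The PHF19 overexpression library alone held a peak at HOXB13, a posterior homeobox gene (chromosome 17, 48724605 to 48724964, 41 fragments, 2.25 per M), at KRT8, an epithelial keratin (34 fragments, 1.87 per M), and at MAF, a transcription factor activated by translocation in some myelomas (10 fragments, 0.55 per M). Away from gene ends, the strongest peak of the empty vector library without a partner lay on chromosome 2 at 13545158 to 13545915, 802424 bp from TRIB2 (214 fragments, 7.82 per M), followed by one inside FMNL2 (147 fragments). Beside the PHF19 peak, the PHF19 overexpression library held one inside DIXDC1, a regulator of WNT signalling (chromosome 11, 111931877 to 111932245, 305 fragments, 16.73 per M). At HOXA9, TNFRSF14, FCGR3A, F2R, FAM177A1 and SLC9A5 for the empty vector library, and at SLC17A7, WNT7B and SLURP1 for PHF19 overexpression, a peak of one library reached the window and an overlapping peak of the other ended just outside it. The one-sided call at these genes thus came from a peak edge and not from the absence of a peak, and F2R also differed in height, as given further on.

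In numbers, 5270 of the 44090 peaks of the PHF19 overexpression library (12.0%, Wilson 95% interval 11.7 to 12.3) had no overlapping peak in the empty vector library, and 10563 of that library's 49155 (21.5%, 21.1 to 21.9) had none in the PHF19 overexpression library. One-sided peaks had a median height of 0.69 fragments per M in both libraries, against 2.3 and 2.48 for shared peaks. At the PHF19 overexpression library's depth, 52.0% of the regions held by the empty vector library alone would have had fewer fragments than 9 in 10 of the peaks called there. Of 19974 protein-coding genes, 226 had a gene-end peak with PHF19 overexpression alone and 379 with the empty vector alone. In 205 and 334 of these the peak itself had no overlap in the other library. With lists cut to equal length the order turned, to 283 and 255 genes. Among the stronger peaks of each list, in the upper 50% by rank, there were 19 and 52 such genes, and 5 and 24 when the peak itself had to lack an overlap. With the summit inside the window the 19 became 64, and the 52 stayed within 1.5 times its value.

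The second comparison puts the same question to the IFN-prefixed pair, which shares no library with the first. Polycomb target genes again stood higher, with a median of 0.22 over the 26 regions (interval 0.0 to 0.33, 99.3rd percentile, 16 above the random median). HOXC13 had a log2 ratio of 0.75 (0.27 to 1.22), MSX1 0.56 (0.16 to 0.94) and PAX2, a kidney and eye transcription factor, 0.97 (0.57 to 1.36), whereas the region shared by HOXA10 and HOXA11 was at -0.49 (-1.14 to 0.11) here and at 0.7 (0.04 to 1.36) in the first pair. With the local median removed the list median was 0.07, at the 63.2nd percentile, against 0.25 and the 99.7th in the first pair, and MSX1 was at 0.05 and HOXD13 at 0.13 (0.39 before). Members with a gene-end peak in one library alone numbered 0 for PHF19 overexpression and 5 for the empty vector (43.5th percentile). MHC class II genes had a median of -0.16 (interval -0.51 to 0.04, 2.7th percentile, and 5.5th with the local median removed), which became 0.01 without centring at the same percentile. CD74 was at -0.51 (-0.68 to -0.35), or -0.11 with the local median removed, HLA-DPB1 at -0.45 (-0.76 to -0.15) and HLA-DQA1, a class II alpha chain, at -0.52 (-0.92 to -0.14). IRF1 was again higher, at 1.29 (1.02 to 1.56), or 0.93 with the local median removed (the bin from 130 to 135 Mb was at 0.31 and 0.35), and IRF4 again lower, at -0.31 (-0.54 to -0.08).

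The lists of broadly active genes lay nearer the middle of the random lists here, a difference between the pairs that was not tested. Housekeeping promoters had a median of -0.02 (34.5th percentile, interval -0.2 to 0.08), the cereblon and proteasome list 0.01 (51.5) and the Polycomb complexes -0.04 (17.3), with EED at -0.48 (-0.89 to -0.1). Cell cycle genes had -0.09 (2.3), a value that became 0.08 without centring, which adds 0.17 to every region and leaves the percentile as it is. Interferon-stimulated genes had 0.09 (81.7), interferon signalling -0.01 (34.4), MHC class I -0.06 (16.4), plasma cell identity 0.04 (69.1) and the B cell programme -0.04 (22.3). IL6 and JAK/STAT3 genes had 0.13 (94.5), myeloma genes 0.03 (65.4), the unfolded protein response -0.03 (27.2), NF-kappaB 0.02 (55.8), immune ligands -0.03 (26.9) and apoptosis regulators -0.05 (17.3). Markers of other cell types had medians of 0.04 for T and NK cells (47.7), -0.03 for myeloid cells (28.7) and 0.26 for stroma and epithelium (84.5). The direction turned with the local median removed for plasma cell identity (-0.08, 4.1st percentile), T and NK cell markers (-0.1, 9.9), cereblon and proteasome (-0.02, 25.4), Polycomb complexes (0.02, 46.6), immune ligands (0.03, 47.8), myeloid markers (0.04, 44.3) and housekeeping promoters (0.02, 60.7). Cell cycle genes were at -0.05 (7.2).

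In this pair 5 interferon-stimulated genes had a gene-end peak in the IFN empty vector library alone and none had one in the IFN PHF19 overexpression library alone. They were GBP1 (43 fragments, 0.65 per M), GBP2, CXCL11, a chemokine that attracts T cells, MX1, an antiviral GTPase, and IFI16, a DNA sensor where an overlapping peak of the other library ended outside the window. The net count lay at the 1.9th percentile of random lists of the same size. These were matched on gene-end peaks in the other 2 libraries and not on height. Of the T and NK cell markers CD2, CD247, TRAT1 and CD3D were on the same side (2.1st percentile), and of the B cell genes CXCR5, ETS1 and CD22 (4.6th percentile). These percentiles come from lists of unequal depth: with equal lists the counts on this side were 2 interferon-stimulated genes and 1 T and NK cell marker, and at a q of 1e-05 they were 5 and 1. GBP2, CXCL11, MX1, TRAT1 and CD3D were named after their values were seen. TRAF3, a brake on NF-kappaB that is often lost in myeloma, had a peak in the IFN empty vector library alone (chromosome 14, 102777225 to 102777727, 170 fragments, 2.58 per M), and so did POU3F2, a neural transcription factor (56 fragments, 0.85 per M), the pro-apoptotic BBC3 (36) and HBA1 (35). The IFN PHF19 overexpression library alone held peaks at CD40, a receptor that activates NF-kappaB (chromosome 20, 46128699 to 46128994, 16 fragments, 0.98 per M), at SPOCK1 (36, 2.2 per M) and at LPAR5, a receptor for lysophosphatidic acid (chromosome 12, 6617787 to 6618177, 43 fragments, 2.63 per M). Away from gene ends the largest one-sided peaks were inside TRIO (chromosome 5, 14281608 to 14282156, 600 fragments, 9.1 per M) and in the pericentromeric part of chromosome 1 for the IFN empty vector library (338 fragments), and inside GABRP for IFN PHF19 overexpression (39 fragments), after the PHF19 peak. At TNFRSF13B, HOXA9, ATF3, TNFRSF14, FCGR3A, EPCAM, F2R, MRPL24, FCER1G and SLURP1 an overlapping peak of the other library ended outside the window.

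The IFN PHF19 overexpression library had 2055 peaks without a partner (4.5%, 4.3 to 4.7) and the IFN empty vector library 26664 (38.2%, 37.8 to 38.5), and gene-end peaks in one library alone numbered 74 and 841 genes. The fragments numbered 65.9 against 16.4 M, and 66.2% of the regions held by the IFN empty vector library alone fell below the depth at which 9 in 10 of the other library's peaks were called. With lists of equal length the counts were 6860 and 7387 peaks and 299 and 337 genes, and with the other empty vector library as the partner 6419 and 10075 peaks and 226 and 361 genes. Of the stronger peaks, 3 and 187 gene ends were one-sided, 2 and 107 of them when the peak itself had to lack an overlap. With the summit inside the window the 3 became 73, and the 187 stayed within 1.5 times its value.

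**Figure D2:**
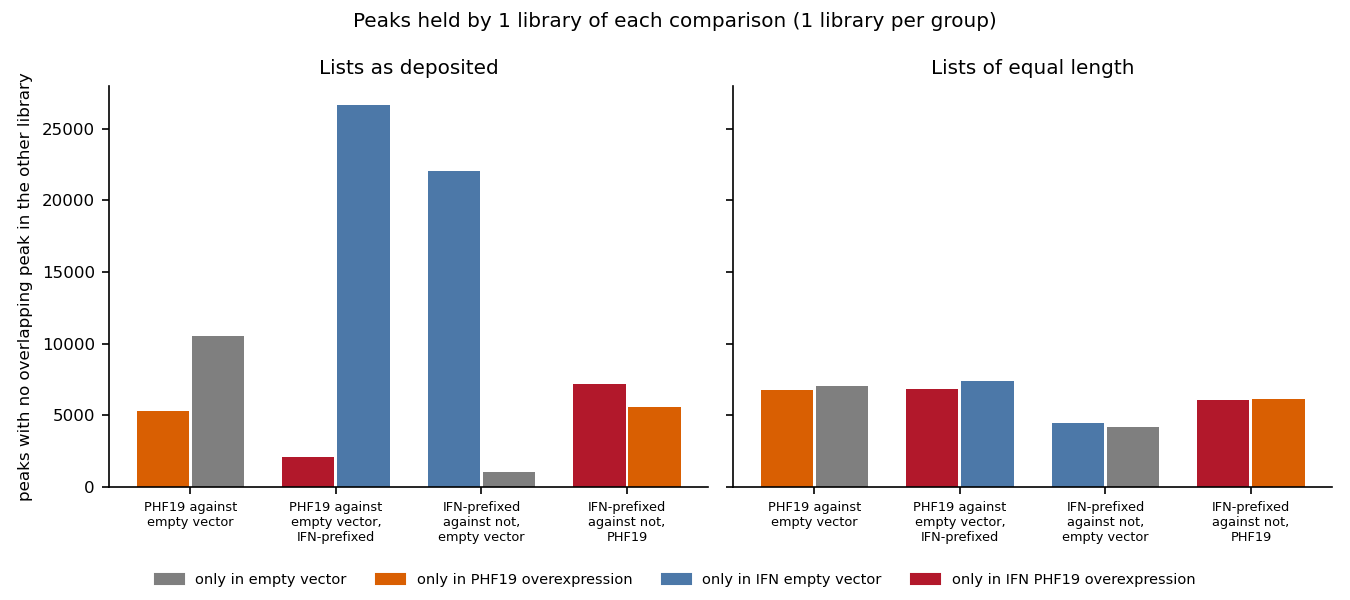
Number of peaks without an overlapping peak in the other library (y axis) for the 4 comparisons (x axis), each bar 1 library, for the lists as deposited and for the 44090 highest-ranked peaks of each library. The 26664 and 22046 peaks of the IFN empty vector library alone become 7387 and 4453 with lists of equal length.

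Both PHF19 comparisons could be set against each other, since they share no library. The gene ends with the largest differences in the same direction in both, picked by size after the data had been seen, included homeobox genes, receptors and enzymes of varied function. Each can be the start or the far end of the gene, so the ratios are not those of promoters alone. NKX2-5, a heart homeobox gene (chromosome 5, region 173234490 to 173235906), was higher, with log2 ratios of 2.9 (2.19 to 3.68) and 3.09 (2.5 to 3.72), going from 0.73 to 5.05 and from 0.52 to 4.95 fragments per M. VAX2, an eye homeobox gene, had 1.41 and 1.38, and the growth factor receptor PDGFRA 1.38 and 1.58, with surrounding medians of 0.6 and 0.56. PRKAG2, a subunit of the energy sensor AMPK (1.95 and 1.66), SNX9, a sorting nexin (2.09 and 1.35), SFTPD, a lung collectin (1.42 and 1.34), and INSYN2B (1.7 and 1.33, with surrounding medians of 0.67 and 0.71) were also among the highest. Lower were CD28, a costimulatory receptor of T cells also found on myeloma cells, at -1.56 (-2.02 to -1.12) and -1.7 (-2.18 to -1.24), and SPI1, a transcription factor of myeloid and early B cells, at -1.59 (-2.39 to -0.87) and -1.48 (-2.22 to -0.81). IL23A, a cytokine subunit, was at -1.44 and -1.54. F2R, the thrombin receptor, was at -1.81 and -1.52, FOXD1, a forkhead gene, at -1.61 and -1.87, and the tyrosine kinase gene FER at -1.53 and -1.43, with surrounding medians of -1.05 and -1.04 at F2R, -0.73 and -0.79 at FOXD1 and -0.57 and -0.52 at FER. With these removed F2R was at -0.76 and -0.48, FOXD1 at -0.88 and -1.07 and FER at -0.96 and -0.91. LCN9 (-1.91 and -1.86) and CCL3L3 (-1.76 and -2.11) were also among the lowest. CCL3L3 is a chemokine gene with near-identical copies, between which short fragments are hard to assign.

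Members of the fixed lists differed alike in both pairs at TNFRSF1A, a receptor for tumour necrosis factor (1.7, 0.68 to 2.78, and 1.74, 0.93 to 2.55), at IL6R, the receptor for the myeloma growth factor IL6 (0.67, 0.4 to 0.95, and 1.03, 0.8 to 1.27, or 0.43 and 0.72 with the local median removed), and at BLK, a B cell kinase (1.02, 0.53 to 1.52, and 0.8, 0.36 to 1.22, 0.58 and 0.34 with the local median removed). The chemokine CCL3 was lower (-0.77, -1.09 to -0.47, and -0.68, -0.97 to -0.41), as were the myeloma surface antigens SLAMF7 (-0.62 and -0.55, and -0.96 and -0.86 with the local median removed) and TNFRSF17 (-0.47 and -0.36). SDC1, the plasma cell marker CD138, was at 0.37 (0.32 to 0.42) and 0.83 (0.78 to 0.87), but at -0.02 in the first pair with the local median removed. FGFR3 and NSD2, which are activated together by a myeloma translocation, were at 0.77 and 0.32 in the first pair and at 1.22 and 0.6 in the second, inside a higher stretch of chromosome 4. With the local median removed NSD2 was at -0.15 and 0.02, and FGFR3 at 0.3 and 0.63. These list members were picked after their values were seen.

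Over the 35731 regions open in all 4 libraries, the log2 ratios of both PHF19 comparisons had a Pearson correlation of 0.63 and a Spearman correlation of 0.57, across regions, which are not independent replicates. The sign was the same in 69.7% of regions. Height was at least 2-fold higher in both pairs in 287 regions, where independent pairs would give 23.4, and at least 2-fold lower in 525, where they would give 30.8. With a floor of 1 fragment per M in all libraries these counts were 62 and 321, and with the local median removed 177 and 425. In 3 regions the direction was opposite. Few regions at least 2-fold different in both pairs were gene ends, 16.7% of the higher and 5.9% of the lower, against 28.3% of all. Gene ends here were the tallest such region of each gene. The shares were not matched on height, so height alone could give part of this difference. Regions held by both empty vector libraries and missing from both PHF19 overexpression libraries numbered 6367, against 3953.4 for independent losses within classes of peak rank, a ratio of 1.61. Regions found with PHF19 overexpression alone in both pairs numbered 430 against 112.0, a ratio of 3.84. With lists of equal length these ratios were 2.35 and 2.07. The PHF19 overexpression library had fewer fragments in both pairs, and loss rates that vary inside a rank class were not simulated. The ratio of 1.61 therefore does not separate a shared loss from losses by depth.

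Part of the shared difference was laid out in long chromosome stretches. Of 524 bins of 5 Mb with at least 20 regions, 30 had a median of at least 0.3 in both PHF19 comparisons and 13 had at most -0.3, on 9 chromosomes. With a floor of 1 fragment per M in all libraries 15 bins were higher. On chromosome 5, the bin from 75 to 80 Mb, which holds F2R, was at -0.91 and -0.99, and the bin from 70 to 75 Mb, which holds FOXD1, at -0.74 and -0.89. The first 5 Mb of chromosome 4, with FGFR3, NSD2, PCGF3 and MSX1, were at 0.48 and 0.55. On chromosome 8 the median of the whole chromosome was 0.28 and 0.23, and the chromosome held 4.72% and 4.79% of peaks with PHF19 overexpression against 4.04% and 4.15% with the empty vectors. The bin medians of both comparisons correlated at 0.9. No bin passed the same limit for the IFN prefix, and chromosome 8 was at 0.02 with either vector. After removal of the local median the correlation over single regions was 0.58. The bins held 6.9% of regions, and 96 of the 287 higher and 87 of the 525 lower regions.

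**Figure D3:**
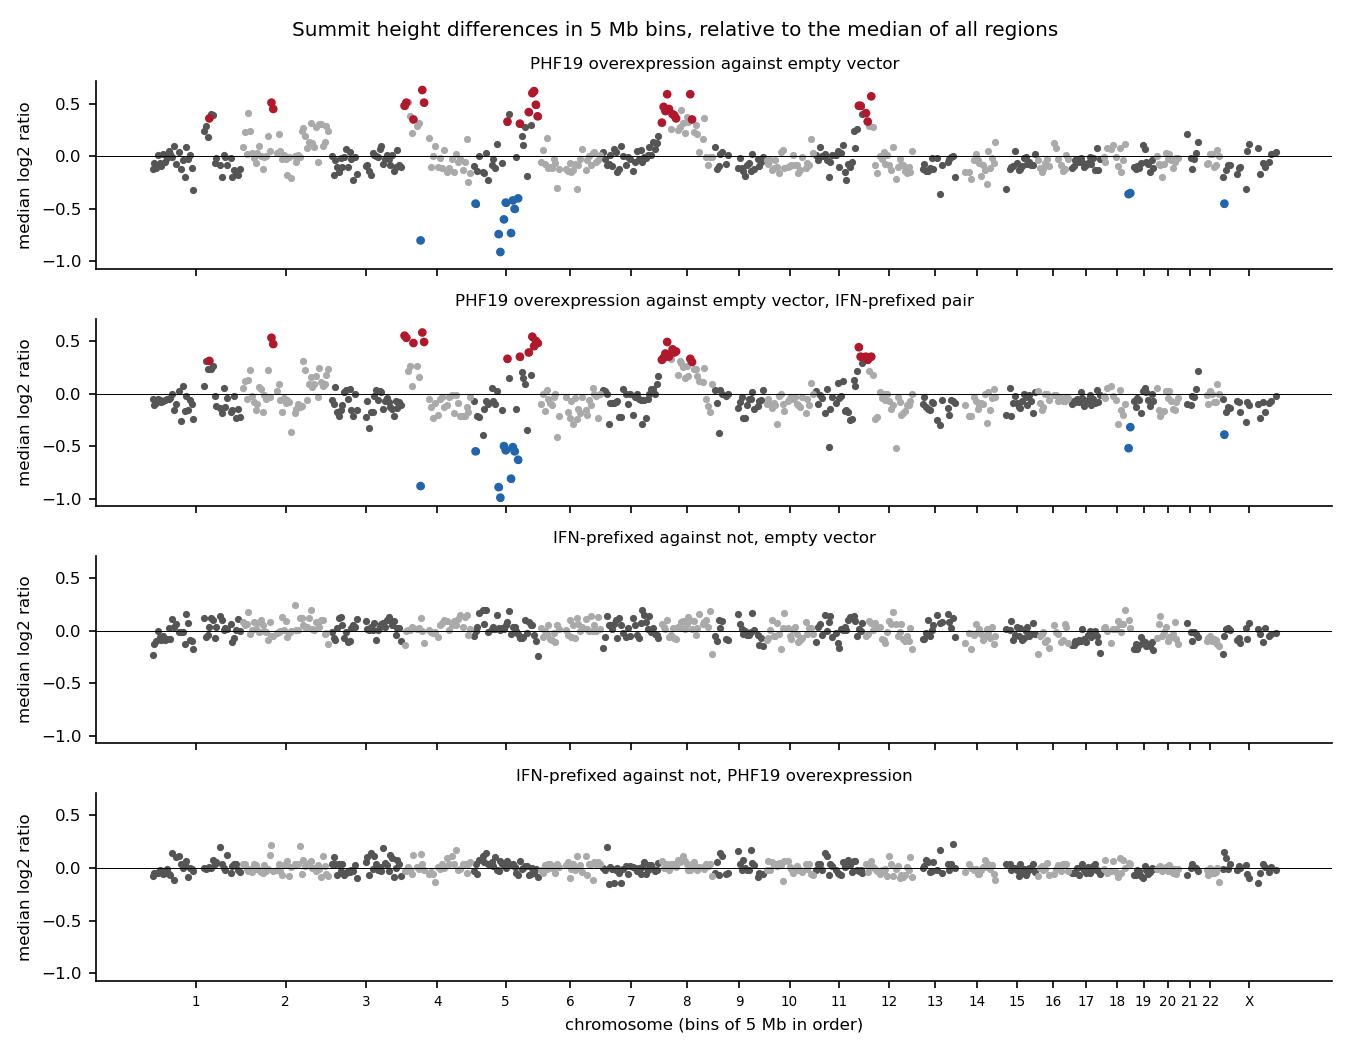
Median log2 height ratio (y axis) of the regions in each 5 Mb bin along the chromosomes (x axis) for the 4 comparisons; each dot is a bin with at least 20 regions, and red or blue marks bins at or beyond 0.3 or -0.3 in both PHF19 comparisons. The 30 higher and 13 lower bins line up between the PHF19 comparisons, while the IFN-prefixed comparisons stay near 0.

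The third comparison sets the IFN-prefixed empty vector library against the other empty vector library. Interferon-stimulated genes stood above comparable genes at their gene ends, with a median of 0.01 over 36 regions where random lists matched on height had -0.14 (99.9th percentile, 28 regions above the random median). Without centring the median was -0.08. GBP4, a guanylate-binding protein, was at 1.05 (0.39 to 1.77), IDO1, the tryptophan-degrading enzyme induced by interferon, at 0.84 (0.1 to 1.64), IFIT2, an antiviral RNA-binding protein, at 0.78 (0.06 to 1.57), and the region shared by PARP9 and DTX3L, partner genes of the antiviral response, at 0.35 (0.06 to 0.65). STAT2, which carries the interferon signal to the nucleus, was at -0.15 (-0.31 to 0.01), or 0.09 with the height trend removed, and IRF1 at -0.29 (-0.58 to 0.0). MHC class II genes lay above comparable genes too, at -0.06 (99.5th percentile, and 0.02 with the local median or 0.11 with the height trend removed), and IL6 and JAK/STAT3 genes lay below them, at -0.3 (1.7th percentile, and -0.22 at the 26.8th with the local median and -0.11 at the 7.7th with the height trend removed), with SOCS2, a feedback inhibitor of cytokine signalling, at -0.56 (-0.77 to -0.35).

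The remaining lists had medians of -0.2 for interferon signalling (53.2nd percentile), -0.15 for MHC class I (88.8), -0.17 for plasma cell identity (77.8), -0.03 for the B cell programme (96.3), -0.23 for Polycomb complexes (8.3), and -0.07 for Polycomb targets (90.7). Further medians were -0.26 for myeloma genes (9.5), -0.24 for cereblon and proteasome (22.2), -0.21 for the unfolded protein response (83.1), -0.22 for NF-kappaB (42.0) and -0.05 for immune ligands (95.9). Apoptosis regulators were at -0.26 (20.4), cell cycle genes at -0.19 (88.7), housekeeping promoters at -0.26 (14.6), T and NK cell markers at -0.17 (27.6), myeloid markers at 0.03 (83.9) and stromal and epithelial markers at -0.08 (49.2). After removal of the local median housekeeping promoters were at -0.18 (76.8), plasma cell identity at -0.21 (29.8) and Polycomb targets at -0.1 (54.6). Peaks in the IFN empty vector library alone stood at GBP2 (36 fragments, 0.55 per M), at the B cell genes ETS1 (24) and CXCR5 (32), at HOXB13 (89 fragments, 1.35 per M), HOXD8 (28), MAF (36), BBC3 (36) and the T cell receptor chain CD247 (48). Another was at TYROBP, an adaptor of myeloid and NK cell receptors (chromosome 19, 35903524 to 35903975, 166 fragments, 2.52 per M). Its strongest one-sided peaks away from gene ends lay inside PDXDC1 (262 fragments) and 369663 bp from FAM174A (221). The empty vector library alone held peaks 229298 bp from LRIG3 (36 fragments, 1.32 per M) and 4265 bp from NKX2-3 (40 fragments, 1.46 per M). IFI16, TNFRSF13B, HBA1, EPCAM, MRPL24, FCER1G, SLC17A7, BAIAP3 and STK3 had a one-sided call that came from a peak edge.

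Here 22046 peaks of the IFN empty vector library (31.6%, 31.2 to 31.9) and 1002 of the other (2.0%, 1.9 to 2.2) had no partner, as did gene-end peaks of 689 and 57 genes. Of the regions held by the IFN empty vector library alone, 63.6% lay below the depth at which 9 in 10 peaks of the other library were called, and with equal lists the counts were 4453 and 4189 peaks and 217 and 184 genes. The file header of the IFN empty vector library also names a different project folder from the other 3, and whether it was processed separately is not known. Strong one-sided gene ends numbered 97 and 3, and 44 and 0 when the peak itself had to lack an overlap. With the summit inside the window the 3 became 72, and the 97 stayed within 1.5 times its value.

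The fourth comparison sets the IFN-prefixed PHF19 overexpression library against the other PHF19 overexpression library, and it shares no library with the third. Interferon-stimulated genes again stood above comparable genes, with a median of 0.15 against -0.06 for random lists (100.0th percentile, 31 of 36 regions above the random median). The PARP9 and DTX3L region was at 0.88 (0.47 to 1.3), IDO1 at 0.9 (0.09 to 1.74), OAS2, which makes the messenger that activates RNase L, at 0.47 (0.11 to 0.84), and STAT2 at 0.33 (0.08 to 0.59). GBP4 at 0.3 (-0.38 to 0.98), IFIT2 at 0.58 (-0.25 to 1.43) and ISG20, a nuclease, at -0.22 (-0.9 to 0.46) had intervals that included 0. MHC class II genes had a median of 0.0 (83.1st percentile), and IL6 and JAK/STAT3 genes had 0.09 (99.8th percentile), with IL21R, a cytokine receptor, at 0.56 (0.14 to 0.99).

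**Figure D4:**
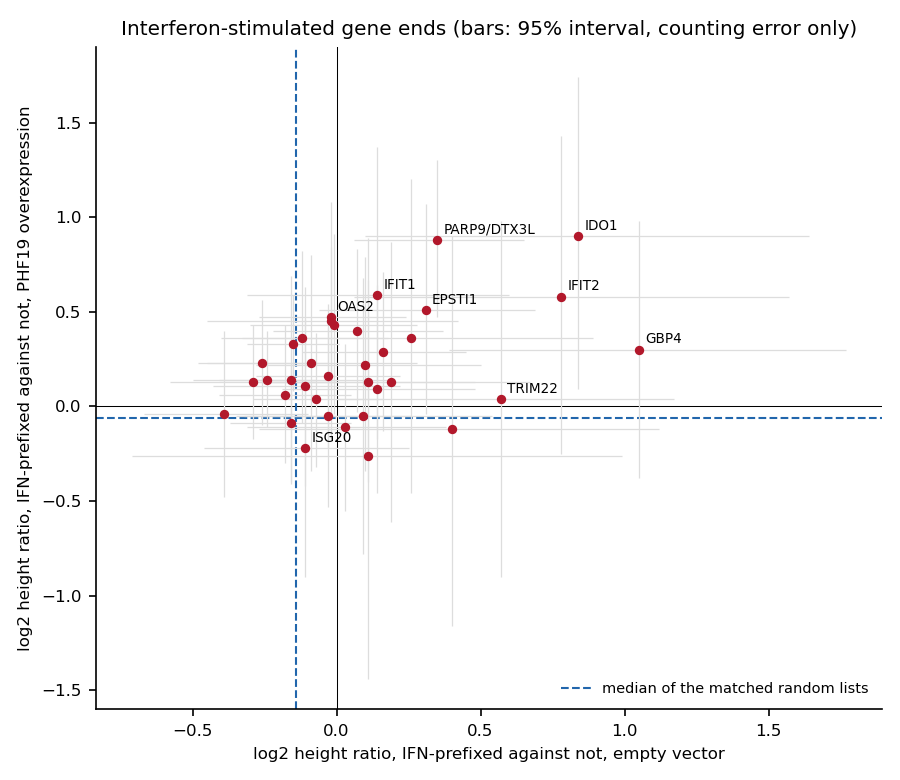
Log2 height ratio at each interferon-stimulated gene end in the IFN-prefixed against the other empty vector library (x axis) and in the IFN-prefixed against the other PHF19 overexpression library (y axis); bars are 95% intervals for counting error and dashed lines the medians of the matched random lists. Of the 36 regions, 28 lie right of the vertical dashed line at -0.14 and 31 above the horizontal one at -0.06.

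Of the other lists, NF-kappaB had a median of 0.02 (93.8th percentile), housekeeping promoters -0.01 (91.7), cereblon and proteasome -0.01 (87.5), immune ligands 0.02 (87.2), MHC class I -0.01 (82.9), the unfolded protein response -0.03 (80.6), and interferon signalling -0.03 (77.0). Polycomb complexes had -0.05 (60.1), apoptosis regulators -0.06 (51.5), Polycomb targets -0.06 (47.1), plasma cell identity -0.07 (42.7), myeloma genes -0.09 (22.6), the B cell programme -0.15 (12.0) and cell cycle genes -0.11 (6.8). Markers of T and NK cells had -0.11 (28.6), of myeloid cells 0.11 (89.8) and of stroma and epithelium 0.18 (93.1). With the local median removed cell cycle genes were at -0.13 (1.6) and apoptosis regulators at -0.11 (8.1). Its removal turned the direction for NF-kappaB (-0.01), MHC class I (0.01), cereblon and proteasome (0.02) and housekeeping promoters (0.02). The IFN PHF19 overexpression library alone held gene-end peaks at IFI44L (18 fragments, 1.1 per M), IRX3, a homeobox gene (13), CD40 (16) and CCL25, a chemokine of thymus and gut (chromosome 19, 8052108 to 8052425, 116 fragments, 7.08 per M). It also held peaks inside DGKG (113) and EGFLAM (69). The PHF19 overexpression library alone held peaks at MX1 (12 fragments, 0.66 per M), TRAF3 (24, 1.32 per M) and TYROBP (49, 2.69 per M), 33362 bp from AMPH (102) and in the pericentromeric part of chromosome 1 (97). The calls at RGS17, FOLR2, SLC30A2 and WNT7B came from a peak edge.

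In this comparison the depths were closest, and 7192 peaks of the IFN PHF19 overexpression library (15.7%, 15.4 to 16.0) and 5550 of the other (12.6%, 12.3 to 12.9) had no partner. Gene-end peaks were one-sided at 227 and 209 genes, and 206 and 170 when the peak itself had to lack an overlap. With lists of equal length both orders turned, to 6053 and 6121 peaks and 197 and 230 genes. Strong one-sided gene ends numbered 18 and 31, and 10 and 8 by the stricter definition. With the summit inside the window they numbered 61 and 72.

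Set side by side, the IFN-prefixed comparisons shared less than the PHF19 comparisons. Their log2 ratios had a Pearson and a Spearman correlation of 0.16 each over the 35731 regions, with the same sign in 56.6%. Height was at least 2-fold higher with both vectors in 13 regions, where independent pairs would give 1.8, and at least 2-fold lower with both in 0. The 13 became 7 with the height trend removed, 5 at a q of 1e-05 and 0 with a floor of 1 fragment per M. The gene ends with the largest differences in the same direction, picked by size after the data had been seen, were on the higher side IDO1, PDCD1LG2, which encodes the checkpoint ligand PD-L2 (0.84, 0.24 to 1.49, and 0.81, -0.03 to 1.68), the atypical receptor gene ACKR5 (0.94, 0.35 to 1.57, and 0.83, 0.03 to 1.66) and LAYN, a hyaluronan receptor (0.69, 0.41 to 0.99, and 0.98, 0.61 to 1.36), with WASHC2C (0.77, 0.13 to 1.47, and 0.98, -0.09 to 2.12) and GSE1 (0.77, 0.19 to 1.39, and 0.76, -0.02 to 1.58). Lower were BAIAP2, a regulator of the actin skeleton (-0.72, -1.06 to -0.38, and -0.72, -1.26 to -0.19), and EEF1D, a translation factor subunit (-0.54, -0.84 to -0.24, and -0.69, -1.21 to -0.18). At least 1 interval included 0 for GRK3, a receptor kinase (-0.74, -1.23 to -0.24, and -0.65, -1.46 to 0.14), PRXL2C (-0.64, -1.17 to -0.11, and -0.61, -1.48 to 0.22), JPH1 (-0.57, -1.26 to 0.15, and -0.77, -1.49 to -0.07) and the dopamine receptor gene DRD1 (-0.54, -1.3 to 0.24, and -0.59, -1.43 to 0.23). Regions found in both IFN-prefixed libraries and in neither of the others numbered 2387 against 1780.4 for independent calls within rank classes (ratio 1.34), and those missing from both numbered 43 against 21.8 (1.98). With lists of equal length these ratios were 1.85 and 1.21. Rates that vary inside a rank class were not simulated for these ratios either.

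**Figure D5:**
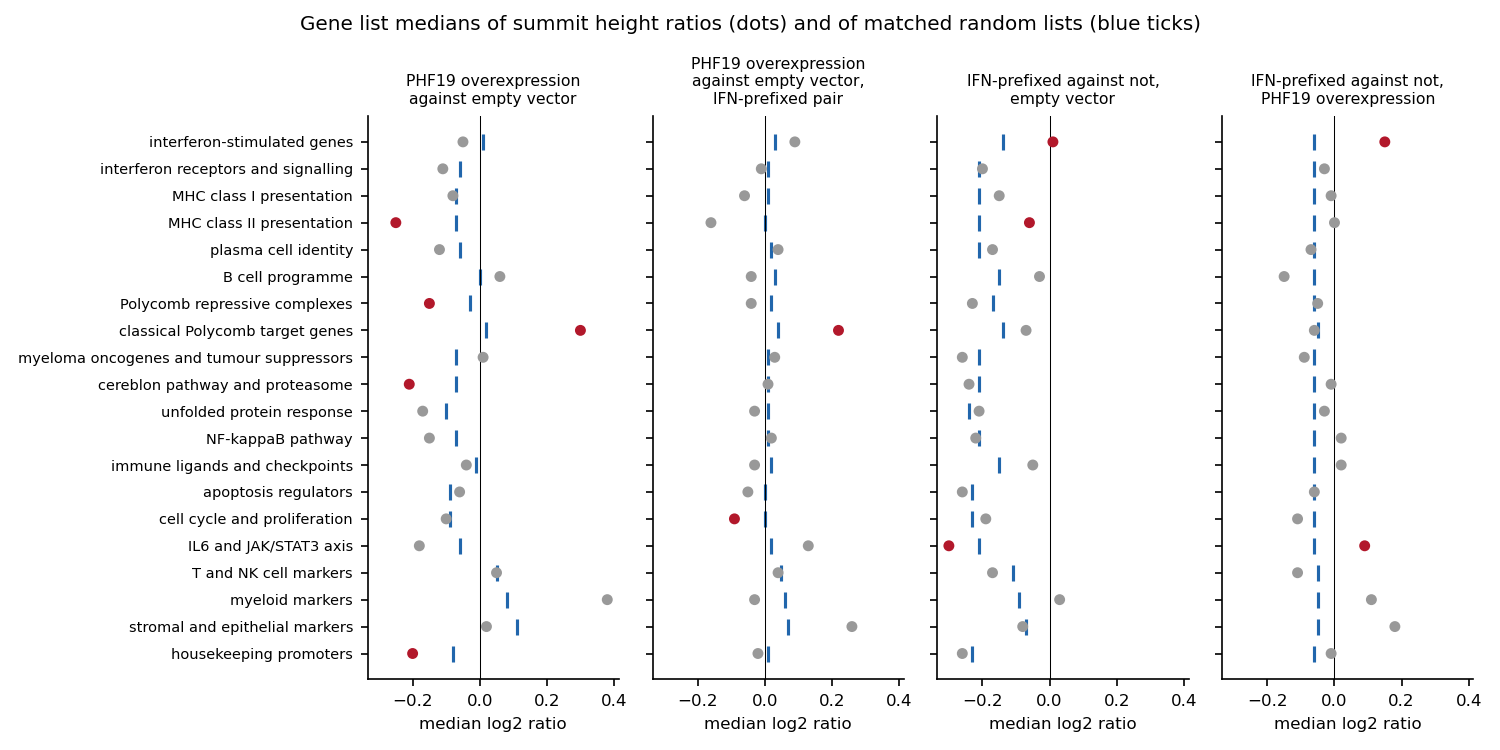
Median log2 height ratio (x axis) of the regions of each gene list (y axis) in the 4 comparisons; dots are the lists, blue ticks the median of 10000 random lists matched on height, and red marks lists outside the central 95% of those. Polycomb targets are red in both PHF19 comparisons, at 0.3 and 0.22, and interferon-stimulated genes in both IFN-prefixed comparisons, at 0.01 and 0.15.

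For the fixed lists, presence of a gene-end peak varied little between libraries. All 30 cell cycle genes and all 28 housekeeping promoters had a peak in every library, as did 24 of 25 interferon signalling genes, 18 of 19 MHC class I genes, 11 of 15 MHC class II genes, 26 of 32 Polycomb complex genes, 22 of 24 cereblon and proteasome genes and 19 of 23 IL6 and JAK/STAT3 genes. These lists had no member on one side in any comparison. The counts that follow are in the order empty vector, PHF19 overexpression, IFN empty vector and IFN PHF19 overexpression. Peaks were present at 39, 37, 42 and 37 of 52 interferon-stimulated genes, at 30, 27, 33 and 28 of 74 Polycomb targets, at 15, 14, 17 and 14 of 24 B cell genes and at 10, 9, 13 and 9 of 24 T and NK cell markers. The Polycomb targets HOXA9, POU3F2, FOXA1 and FOXA2 had a gene-end peak with the empty vector and not with PHF19 overexpression in both pairs, at HOXA9 and, in the first pair, FOXA2 by a peak edge. FOXA1 and FOXA2 were named after their values were seen. Plasma cell genes had peaks at 22, 22, 23 and 22 of 24, myeloma genes at 26, 27, 27 and 26 of 28, and unfolded protein response genes at 23, 22, 23 and 22 of 24. NF-kappaB genes had peaks at 19, 19, 19 and 20 of 24, immune ligands at 17 of 26 in each library and apoptosis regulators at 23, 23, 24 and 23 of 25. Markers of other cell types were mostly closed, with peaks at 7, 7, 8 and 6 of 22 myeloid, 4, 3, 4 and 3 of 16 erythroid and 6, 7, 8 and 7 of 20 stromal and epithelial genes. The erythroid list had too few shared regions for a height median.

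Most one-sided peaks lay away from genes' ends. Peaks at gene ends made up 23.4% of the empty vector list, 25.5% of PHF19 overexpression, 17.9% of the IFN empty vector and 24.7% of IFN PHF19 overexpression, with 38.5%, 37.0%, 40.3% and 37.6% elsewhere inside genes. Of the one-sided peaks in the first comparison 5.4% and 5.0% lay at gene ends, for PHF19 overexpression and empty vector in turn, against 28.2% and 28.4% of shared peaks. In the other comparisons the share of one-sided peaks was between 4.6% and 7.8%, against 23.7% to 28.5% of shared peaks. One-sided peaks were also lower than shared peaks in every comparison, and these shares were not matched on height.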

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

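Among the tests in this part, those of copy number within the blocks, of a trend with peak height and of a height floor were planned before their results were seen, and all others were chosen only after the result was seen. The limits that pick out the IL6 and JAK/STAT3 list, below the 10th or above the 90th percentile in opposite directions, were also set after its values were seen.

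The IL6 and JAK/STAT3 genes, the signalling axis of a main myeloma growth factor, were on opposite sides in the 2 pairs. With PHF19 overexpression their median log2 ratio was -0.18 (3.4th percentile, interval over regions -0.28 to 0.2) in the first pair and 0.13 (94.5th, -0.09 to 0.28) in the IFN-prefixed pair, with VEGFA at -0.45 and 0.07 and IL21R at -0.63 and -0.07. With the IFN prefix it was -0.3 (1.7th percentile, -0.34 to -0.15) with the empty vector and 0.09 (99.8th, -0.16 to 0.16) with PHF19 overexpression. The opposite signs stayed under other settings while some values passed the percentile limits. With the local median removed the IFN-prefix values were -0.22 (26.8th) and 0.1 (99.9th) and the PHF19 values -0.14 (7.0th) and 0.13 (96.2nd), and with the height trend removed the PHF19 values were -0.05 (10.4th) and 0.15 (92.1st). These are not separate findings, since all 4 values come from the same 4 libraries, and the difference was not tested. Among single regions open in all libraries, 3 were at least 2-fold higher with PHF19 overexpression in one pair and at least 2-fold lower in the other, a difference that was not tested either.

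Height differences with PHF19 overexpression recurred in both pairs and were partly grouped in chromosome blocks. A difference in copy number between the transfected populations predicts that gene ends and other regions in a block shift by a like amount, and the smallest of the 4 ratios of their medians was 0.73, consistent with such a difference, though copy number was not measured. Blocks as the only source are argued against by the correlation of 0.58 that was left between the pairs after the local median was removed, and a trend with peak height by the 0.63 that was left after the trend was removed. What stays open for the remaining regions is PHF19 itself, any other difference between the 2 cell populations, and a difference in depth or library quality. The labels do not say whether both pairs came from the same transfections. The PHF19 overexpression library had fewer fragments in both pairs, 18.2 against 27.4 M and 16.4 against 65.9 M, so depth cannot be separated from PHF19 here.

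Interferon-stimulated gene ends stood above comparable genes in the IFN-prefixed libraries with both vectors. The heights of the IFN empty vector library, which differs in depth and project folder, enter only the ratios of the comparison that uses it. The list was at the 100.0th percentile in the PHF19 overexpression libraries, whose ratios do not include it and which share a project folder per the file headers. The choice of regions and the matching on height used all 4 libraries, so an influence by that route stays open. Regions called only because they are strong in one library are argued against by the same percentile, 100.0, with a floor of 1 fragment per M in all libraries. An interferon treatment is a candidate explanation as a hypothesis, since the labels do not state what the prefix means and other differences between the libraries stay untested.

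A peak inside PHF19 was called in both PHF19 overexpression libraries and in neither empty vector library. The depth of the empty vector libraries is argued against, because at the same height the peak would have had at least 20.1 times the fragments of the lowest peak called there (201 and 483 fragments expected), and a gain of the whole locus is argued against by the other 4 peaks, whose median log2 ratio was at most -0.2. Reads from the PHF19 sequence on the vector might give such a peak, with edges fixed by the inserted sequence: both edges lay within 10 bp of each other in the 2 libraries, as in 4.5% of 6863 peaks of like height and in 12.9% of the 70 of those no longer than 500 bp. Peak length thus sets part of this closeness, and as exon positions were not used here, vector reads and an opening of the chromosome cannot be told apart.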

How the results depend on the processing

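The alternatives named at the end of the methods as added after the data had been seen, and all settings for heights, strong gene ends and chromosome shares, were chosen after seeing the data. Of 698 alternative values 607 were unchanged, 85 moved and 6 reversed. Heights at single named genes made up 356 of these values. Of the other 342, 258 were unchanged, 78 moved and 6 reversed. Unchanged values stayed within 1.5 times a count or within the interval of a value. A value whose interval included 0 could change sign and still count as unchanged. The MHC class II median in the IFN-prefixed pair did so without centring. Strong gene ends were not checked for a turn in order, so their turns are not among the reversed values. Correlations were given no interval and counted as unchanged within a fixed tolerance around the main value. Correlations (14 of 14), peaks per library (8 of 8), chromosome 8 shares (12 of 12), heights at named genes (349 of 356) and list medians (53 of 56) had the largest share of unchanged values. A list median counts as unchanged inside its own interval, which can hide a shift in percentile. With the local median removed, T and NK cell markers in the first pair went from the 49.5th to the 0.5th percentile (0.05 to -0.27), plasma cell identity in the IFN-prefixed pair from the 69.1st to the 4.1st (0.04 to -0.08), NF-kappaB genes in the first pair from the 10.2nd to the 73.3rd and housekeeping promoters between the empty vector libraries from the 14.6th to the 76.8th. Polycomb targets in the IFN-prefixed pair went from the 99.3rd to the 63.2nd, MHC class II genes in the first pair from the 1.2nd to the 10.1st and IL6 and JAK/STAT3 genes between the empty vector libraries from the 1.7th to the 26.8th. Among 536 values of list members 514 stayed within their interval, 21 moved and 1, SDC1, reversed, at -0.02 with the local median removed. No paired test was run. The pairs were set against each other region by region, and an additive fit over all 4 libraries, with 1 library per group, was not run. The alternative of every transcript start and all sequence motif settings were not run, for want of transcripts and a genome. Depth limits the one-sided counts, and several of them also moved with the overlap rule, as given below. For the changes that follow the cause was not tested, except that equal lists shorten the longer list by construction.

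At a q of 1e-05, one-sided peaks fell to 3250 from 5270 for PHF19 overexpression, to 1283 from 2055 for IFN PHF19 overexpression against its empty vector, to 417 from 1002 for the empty vector against the IFN empty vector and to 3685 from 5550 for PHF19 overexpression against IFN PHF19 overexpression. Genes with a peak in the empty vector and not the IFN empty vector library were 25 (57), T and NK markers in the IFN empty vector library alone 1 (4), regions with PHF19 overexpression alone in both pairs 242 (430), regions missing with the IFN prefix 18 (43) and regions higher with it 5 (13). Gene-end shares were 25.4%, 28.7%, 19.6% and 27.1% in the order empty vector, PHF19 overexpression, IFN empty vector and IFN PHF19 overexpression (23.4%, 25.5%, 17.9% and 24.7%).

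With equal lists, the empty vector library alone held 7037 peaks (10563) against PHF19 overexpression. The IFN-prefixed pair had 6860 and 7387 (2055 and 26664), and the empty vector libraries 4453 and 4189 (22046 and 1002). Between the PHF19 overexpression libraries the order reversed, to 6053 and 6121 peaks (7192 and 5550) and 197 and 230 genes (227 and 209). It also reversed for genes in the first pair, 283 and 255 (226 and 379). Genes were 299 and 337 in the IFN-prefixed pair (74 and 841) and 217 and 184 between the empty vector libraries (689 and 57). Strong gene ends were 8 and 73 in the IFN-prefixed pair (3 and 187) and 39 for the IFN against the other empty vector library (97). List members in the IFN empty vector library alone were 2 interferon-stimulated genes (5), 3 Polycomb targets (5) and 1 T and NK marker (4). Recurrent regions were 2855 missing with PHF19 overexpression (6367), 2098 with it alone (430), 591 missing with the IFN prefix (43) and 702 with it alone (2387). Gene-end shares were 25.4% for both empty vector libraries and 25.5% for IFN PHF19 overexpression.

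With an overlap of 50% each way, 8427 peaks were found with PHF19 overexpression alone (5270), 9307 with IFN PHF19 overexpression alone (2055) and 5799 with the empty vector against the IFN empty vector (1002), and recurrent regions were 1891 with PHF19 overexpression alone (430) and 659 missing with the IFN prefix (43). Without the IFN empty vector library, with the other empty vector library as partner of IFN PHF19 overexpression, peaks were 6419 and 10075 (2055 and 26664) and genes 226 and 361 (74 and 841).

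With the summit inside the window, strong gene ends were 64 for PHF19 overexpression (19), 73 for IFN PHF19 overexpression against its empty vector (3), 72 for the empty vector against the IFN empty vector (3), 61 for IFN PHF19 overexpression against PHF19 overexpression (18) and 72 for the reverse (31). Genes were 187 for IFN PHF19 overexpression (74) and 147 for the empty vector against the IFN empty vector (57), Polycomb targets in the IFN empty vector library alone 2 (5), and gene-end shares 21.7%, 23.9%, 16.3% and 23.1% in the order above. When the peak itself had to lack an overlap, strong gene ends were 5 and 24 in the first pair (19 and 52), 107 for the IFN empty vector against IFN PHF19 overexpression (187), 44 and 0 between the empty vector libraries (97 and 3) and 10 and 8 between the PHF19 overexpression libraries (18 and 31). A window of 2000 bp gave 2 Polycomb targets with the empty vector alone (4) and 6 strong gene ends of the empty vector against the IFN empty vector (3). A window of 500 bp gave 1 and 2 Polycomb targets in the first and the IFN-prefixed pair (4 and 5), 9 such strong gene ends (3) and 30 for IFN against the other PHF19 overexpression library (18).

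For heights, removal of the local median left 177 regions higher with PHF19 overexpression in both pairs (287), and removal of the height trend left 7 higher with the IFN prefix (13). Without centring the Polycomb target median in the IFN-prefixed pair was 0.39 (0.22), and that of the IL6 and JAK/STAT3 list -0.29 and 0.3 (-0.18 and 0.13). With at least 1 fragment per M in all libraries, 62 regions were higher (287) and 321 lower (525) with PHF19 overexpression, 0 were higher with the IFN prefix (13) and 15 bins were higher (30).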

Other observations

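No test was run for this part. The median peak length was 739 bp in the empty vector library, 685 bp with PHF19 overexpression, 771 bp in the IFN empty vector library and 667 bp with IFN PHF19 overexpression. Over all summits, including several within a peak, the median height was 50, 38, 72 and 36 fragments in the same order, or 1.83, 2.08, 1.09 and 2.2 per M.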
